A study of Homo sapiens with 6 samples.

How the data were processed

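Total RNA from MDA-MB-231 cells, a human triple-negative breast cancer line, had been labelled with biotin and hybridised to Illumina HumanHT-12 V4 bead arrays. The 6 arrays form 6 groups of 1 array each, so no group has a replicate of its own. Per the labels, the cells were untreated, transfected with a vector for LSD1 (gene KDM1A), or cultured for 24 hours with the LSD1 inhibitor ORY1001. Each state was measured without and with 2 Gy of X-rays. The labels write the inhibitor's dose as 10 with a unit that reads as micrometre and was taken as micromolar. They give a collection time only for the irradiated ORY1001 cells, at 4 hours after irradiation.

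The deposited files were made with GenomeStudio 2011.1, per the submitters' processing notes. One deposited table holds the mean bead intensity of each probe on each array, without normalization. A deposited p-value stands beside each intensity, the detection p-value, which is the share of negative control probes at least as bright as the probe. Its smallest value above 0 implies about 770 such controls. A further table from the authors holds the same intensity after background subtraction and scaling of each array to a mean of 355.77, with bead numbers and linear ratios of pairs of arrays. The authors' ratio columns are quotients of background-subtracted signals, so some are below 0. The deposited series values equal these scaled signals to within 5e-10, and each value rests on 1 array. The array means of the unscaled intensity lay between 389.1 and 421.9, and the median number of beads per probe between 20 and 22. The number of arrays limits the precision of every value.

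The tables hold 47317 probes. The 92 control probes with a non-human annotation were left out, which left 47225 human probes. Names came from a reference table through the gene identifier for 35668 probes and through the transcript accession for 85. A further 8203 probes kept the symbol in the file and 3269 had none. The unscaled intensities were corrected with limma's neqc function (version 3.58.1, R 4.3.3), which models the background from negative controls inferred from the detection p-values. It adds an offset of 16, applies quantile normalization and gives log2 signals. A probe was kept with a detection p-value under 0.01 on at least 2 arrays, and each gene was represented by its probe with the highest mean signal. This gave 14831 genes, of which 14109 had a symbol and 722 were probes without one. The lowest detected log2 signal lay between 5.08 and 5.37 on the 6 arrays. Where one side of a difference was not detected on any of its arrays, the fold is given as a lower limit against the arrays' lowest detected signals. A gene with only some undetected arrays on a side keeps its fitted difference, which then includes signals not above background. Counts by size use the signals as computed, detected or not.

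The following choices were made before the data were examined. Averaged effects of overexpression, ORY1001 and irradiation were tested with limma in an additive model of LSD1 state and irradiation, which leaves 2 residual degrees of freedom. Any dependence of one factor on the other counts as spread in this model. The moderated test had 4.52 prior degrees of freedom, and the SE of a typical gene was 0.22 for overexpression or ORY1001 and 0.18 for irradiation on the log2 scale. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over all genes. A single pair of arrays has no test. A log2 difference of at least 1 in a pair, which is 2-fold, was counted as a rule of size. Agreement was computed across genes between pairs that share no array.

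The study's factors, the cell line and possible other cell types led to 22 gene lists. Each list was described by the median log2 difference of its measured members and by its percentile among 10000 random lists of the same size matched for expression. A percentile under 2.5 or over 97.5 is called standing apart, which is not a test. The p-values of members were also adjusted over the list alone. This adjustment does not account for the 22 lists or for the several averaged effects, so a member that passes it can still be a chance result. The named genes followed a rule. For each averaged effect these were the 12 higher and 12 lower genes whose smallest difference over the pairs was farthest from 0. For irradiation in each LSD1 state these were the 5 highest and 5 lowest genes. Up to 4 members with the farthest averaged effect were named for each list, and KDM1A always. Second probes of genes were compared after the arrays had been seen, for the 3634 genes with another detected probe.

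The models were tested on simulated data with 14831 genes and 200 changed genes. Of 50 genes changed 2-fold by overexpression, 2 were called, and of 50 changed 4-fold, 46 were called. Without any simulated change no gene was called. The simulated effects were additive and each gene had 1 spread on all arrays, whereas 1 of the real arrays stood apart. The shares called therefore do not carry over to the real genes. There, IL6 and CSF3 were not called at 5.47-fold and 5.80-fold higher with overexpression, while DDX60 was called at 4.71-fold. Among 1000 simulated unshifted lists, 51 stood apart, and among 1000 lists shifted by 0.3 on the log2 scale, 970 did. The simulated genes varied independently of each other, so these shares do not carry over to lists whose members vary together. The alternatives covered background correction, normalization, the deposited signals, the detection filter, the choice of probe, the moderation, the model, the size rule and leaving out each array. A correction for probe GC content was chosen after seeing the data. Medians and lists were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.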

Results

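Expression of 14831 genes was compared in MDA-MB-231 cells that were untreated, transfected with a vector for the histone demethylase LSD1, or cultured with its inhibitor ORY1001, each without and with 2 Gy of X-rays. Between 17619 and 19495 human probes were detected per array, 37.3% to 41.3% of all. The unirradiated ORY1001 array correlated with its nearest array at r = 0.970 across genes, while each other array reached 0.989 to 0.991 with its nearest. The genes are not independent replicates, so these correlations have no p-value. Values are differences of log2 signal. An error is the SE of the limma model, with 2 arrays against 2 for LSD1 states and 3 against 3 for irradiation. Single pairs have no error of their own. A gene is said to have risen or fallen where its adjusted p was under 0.05 over all genes or, where stated, adjusted over the list alone.

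LSD1 itself is encoded by KDM1A. Its probe ILMN_1813840 lies on chromosome 1 (1p36.12a) from 23282589 to 23282638 on the plus strand of a genome build that the files do not name. It starts at base 2848 of the transcript. In overexpressing cells KDM1A differed from untreated cells by -0.01 without and by -0.15 with irradiation (average -0.08 ± 0.26, adjusted p = 0.972). In ORY1001 cells it differed by 0.67 and -0.21 (average 0.23 ± 0.26, adjusted p = 0.888). After irradiation it differed by 0.16 in untreated, 0.02 in overexpressing and -0.71 in ORY1001 cells (average -0.18 ± 0.21, adjusted p = 0.816). The authors' ratio of overexpressing to untreated cells was 1.02. The files do not give the vector's sequence, so a vector transcript without the probed end of the gene would go unseen. The cells are called overexpressing after the labels, and the arrays themselves do not show a higher LSD1 level.

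**Figure D1:**
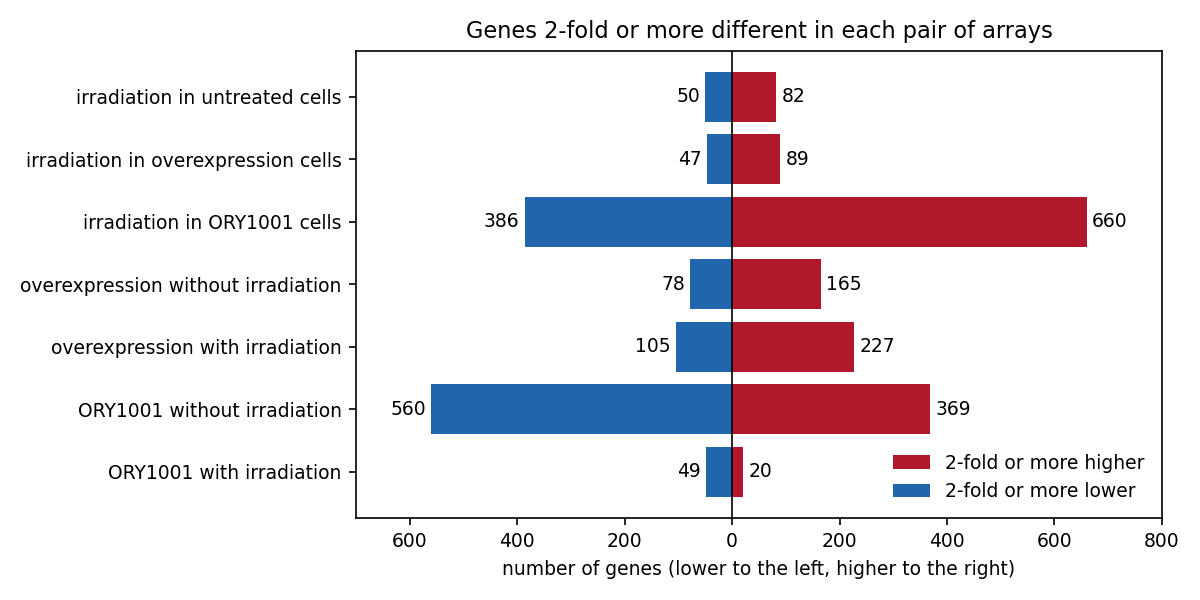
Number of genes at least 2-fold higher (red bars, to the right) or lower (blue bars, to the left) out of 14831 genes (horizontal axis) in each of the 7 pairs of arrays (vertical axis). The pairs with the unirradiated ORY1001 array hold 1046 and 929 such genes, and the other pairs between 69 and 332.

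Cells labelled as LSD1 overexpression were compared with untreated cells, which the labels set against each other by the LSD1 vector. Interferon-stimulated genes and inflammatory cytokines were higher in overexpressing cells in both irradiation states. TFF1, a secreted trefoil factor typical of luminal breast epithelium, rose at least 8.21-fold from a signal below detection. MUC5AC, a gel-forming mucin, rose by 2.71 ± 0.21, and DDX60, an interferon-stimulated helicase, rose by 2.23 ± 0.18. Each was higher in both pairs. Cholesterol and fatty acid synthesis genes and cell cycle genes were lower, as lists, in both pairs.

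These 3 genes rose in limma over all genes tested (adjusted p = 0.0458 for each), no gene fell, and 1257 genes had an unadjusted p under 0.05 where chance gives 742. The count was 481 without either ORY1001 array, when the remaining arrays of the comparison set the spread, and 35 and 7 without the unirradiated and the irradiated overexpression array. It was 1, TFF1, without the unirradiated untreated array and 0 without the irradiated one. The 24 genes named by rule for overexpression were chosen for large differences in both overexpression pairs. Without an ORY1001 array those pairs alone set the spread, so that fit gives these genes no separate support.

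The other genes named as higher, in both pairs, included further inflammatory signals. The acute-phase cytokine IL6 was higher by 2.45 ± 0.38, the granulocyte growth factor CSF3 by 2.54 ± 0.39 and the chemokine CCL20 by 2.09 ± 0.28 (adjusted p of 0.130, 0.130 and 0.0919). The interferon-induced GTPase GBP4 was higher by 2.42 ± 0.23, OASL by 2.27 ± 0.25 and the interleukin receptor IL7R by 1.92 ± 0.21 (adjusted p = 0.0788 each). LOC100132635 was higher by 2.28 ± 0.21, the membrane protein MAL2 by 2.14 ± 0.24 and the aldo-keto reductase AKR1C2 by 2.17 ± 0.32. Among the 12 lower genes were CDH4, a cadherin, at -2.16 ± 0.33 and AOX1, aldehyde oxidase, at -1.81 ± 0.19. DKK1, a secreted Wnt antagonist, was at -1.50 ± 0.19 and the actin-binding NEXN at -1.45 ± 0.19. The metastasis suppressor KISS1 was at least 2.01-fold lower, MARCHF4 at least 2.02-fold and ANOS1 at least 1.90-fold. The others were LOC728285 (-1.74 ± 0.19), HHIP-AS1 (-1.58 ± 0.19), RBM24 (-1.65 ± 0.33), CPA4 (-1.52 ± 0.26) and LOC728934, at least 1.62-fold lower. No lower gene passed the threshold.

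Interferon-stimulated genes had a median difference of 0.73 without and 1.13 with irradiation (average 0.90, percentile 100 in all 3). Adjusted over the list alone, 31 of 49 measured members rose and none fell, against 1 over all genes, and 47 were higher in both pairs. OASL rose by 2.27 ± 0.25, the exonuclease ISG20 by 2.06 ± 0.23 and IFI44L by 1.93 ± 0.21 (limma, adjusted p = 0.000589 each over the list alone). The brightest probe of OAS1 differed by 0.30 and -0.13, and its second probe by 1.15 and 1.13. NF-kB and inflammatory cytokine genes had medians of 0.61 and 0.73 (average 0.58, percentile 100 in all 3). Adjusted over the list alone, 11 of 29 rose, against 0 over all genes. They included CSF3, IL6, CCL20 and the growth factor CSF2 (1.93 ± 0.23), each with a limma adjusted p = 0.00284 over the list alone. Beside both lists, luminal breast markers had medians of 0.34 (percentile 99.95) and 0.21 (98.1), and 4 of 13 rose adjusted over the list alone. These were TFF1, AGR2 (1.23 ± 0.20), TFF3 (1.16 ± 0.18) and the transcription factor SPDEF (0.97 ± 0.26), of which TFF1 also rose over all genes. Fibroblast markers had an average median of 0.08 (percentile 70.8) and blood markers of 0.19 (92.3), with 5 measured members each and none that rose or fell.

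Histone genes had medians of 0.34 and 0.61 (average 0.37, percentile 99.99), and 5 of 15 rose adjusted over the list alone, against 0 over all genes. H2BC21 rose by 1.35 ± 0.26, H2BC5 by 1.10 ± 0.21, H2AC6 by 0.99 ± 0.19 and H2AC18 by 0.98 ± 0.21. These genes can make polyadenylated transcripts outside S phase. Cholesterol and fatty acid synthesis genes had medians of -0.30 and -0.40 (average -0.33, percentile 0), and 4 of 30 fell adjusted over the list alone, against 0 over all genes. Among these, fatty acid synthase FASN fell by 1.14 ± 0.20, the desaturase SCD by 1.03 ± 0.19 and DHCR7 by 0.93 ± 0.20. G1/S and DNA replication genes had an average median of -0.28 and G2/M and mitosis genes of -0.24, both at percentile 0. Of these, 29 of 34 and 28 of 35 were lower in both pairs, with none past the threshold adjusted over the list alone or over all genes. CHAF1A differed by -0.62 ± 0.18 and AURKB by -0.61 ± 0.19. DNA double-strand break repair genes had an average median of -0.19 (percentile 0.050), while CHEK2, a checkpoint kinase, rose by 0.94 ± 0.18 adjusted over the list alone, and no member passed over all genes.

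Immediate early genes, the fast transcriptional response to stimuli, had an average median of 0.35 (percentile 100). Their median was 0.36 (100) without and 0.14 (99.7) with irradiation. Adjusted over the list alone, 4 of 31 rose, among them RHOB (1.40 ± 0.22), KLF4 (1.28 ± 0.19) and JUNB (1.08 ± 0.25). Unfolded protein and amino acid stress genes had an average median of 0.21 (percentile 100). GDF15, a stress cytokine, rose by 1.64 ± 0.26 and the chaperone DNAJB9 by 1.16 ± 0.21, 2 of 34 adjusted over the list alone. Hypoxia and glycolysis genes had 0.12 (percentile 99.8), and 3 of 32 rose adjusted over the list alone: ANGPTL4 (1.41 ± 0.20, its second probe at 1.13 and 0.47), SLC2A3 (0.97 ± 0.21) and P4HA2 (0.86 ± 0.19). Epithelial genes had 0.16 (percentile 98.7), and 1 of 16, PKP3, rose by 1.09 ± 0.24. Mesenchymal genes had 0.08 (percentile 92.9), with 0.16 (98.96) without and 0.08 (91.8) with irradiation, and 1 of 20 rose. TGF-beta and YAP targets had an average median of -0.01 (percentile 56.5), with 0.16 (98.6) without and -0.07 (28.0) with irradiation. Of these, BHLHE40 rose by 1.35 ± 0.26 and the vasoconstrictor EDN1 fell by 1.03 ± 0.22, 2 of 21. Each rise or fall in these 6 lists is adjusted over the list alone, and none of their members passed over all genes. The averages of the remaining lists did not stand apart and had no member past the threshold either way. KDM1A and partners had an average median of -0.02 (percentile 54.3), ribosomal proteins -0.06 (11.8) and oxidative phosphorylation -0.02 (60.9). Heat shock and oxidative stress genes had -0.00252 (67.9), with 0.14 (99.6) without and -0.05 (31.1) with irradiation. The p53 targets had an average median of 0.09 (95.0) and genes known to rise on LSD1 inhibition in other cell types of 0.19 (95.8).

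Both overexpression pairs, which share no array, correlated at 0.531 across genes. Of the genes at least 2-fold higher, 165 without and 227 with irradiation, 97 were shared where independence gives 2.53. Of the 78 and 105 lower genes, 22 were shared where independence gives 0.552. Of the 2-fold genes with a second probe, that probe differed in the same direction for 38 of 39 without and 61 of 62 with irradiation. Over all genes with a second probe the shares were 67.6% and 70.9%.

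**Figure D2:**
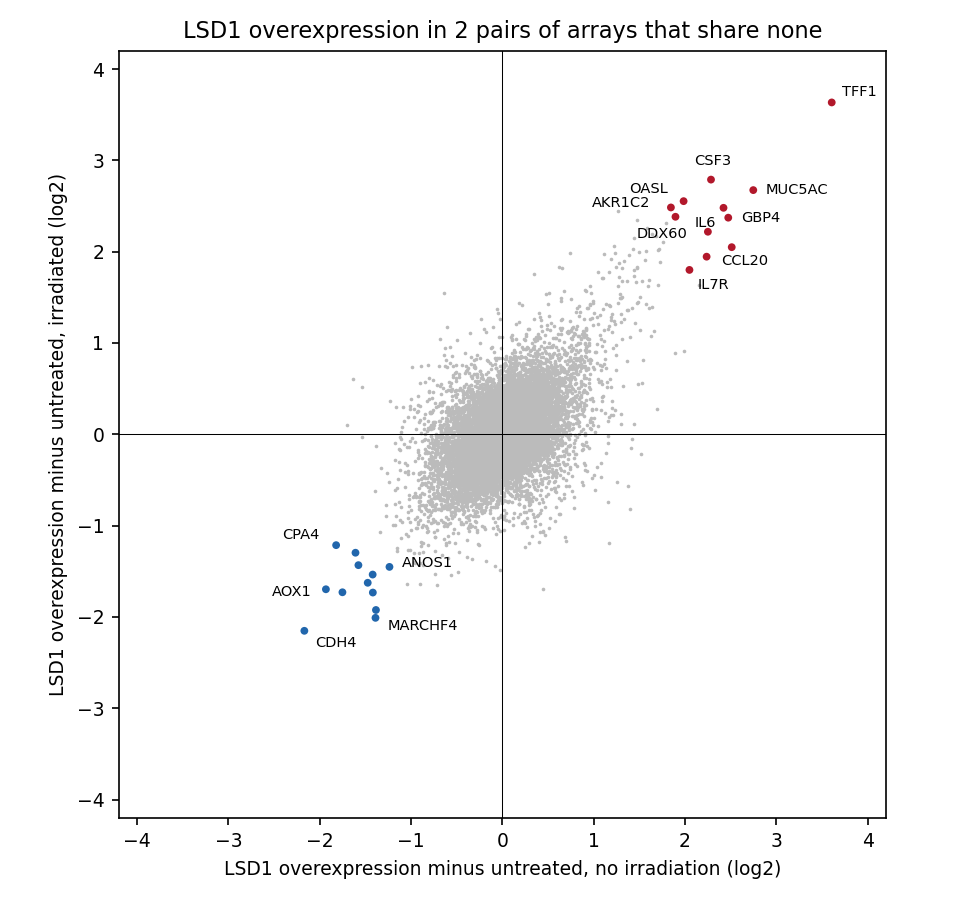
Log2 difference of each gene between overexpressing and untreated cells without irradiation (horizontal axis) and with irradiation (vertical axis), with 12 higher (red) and 12 lower (blue) genes chosen by rule and all others in grey. Points gather along the diagonal, with a correlation of 0.531 across genes, and TFF1, MUC5AC and DDX60 lie in the upper right.

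ORY1001 was compared with untreated cells to ask which genes follow the inhibition of LSD1. The 9 measured genes of 20 known to rise on LSD1 inhibition in other cell types, myeloid and Notch genes, were higher as a list in both irradiation states. Their median was 0.68 (percentile 99.9) without and 0.39 (99.96) with irradiation, and 0.32 (99.4) for the average. The Notch target HES1 rose by 1.18 ± 0.22, the monocyte receptor CD14 by 0.80 ± 0.19 and CSF1R by 0.75 ± 0.20, adjusted over the list alone (p of 0.0124, 0.0216 and 0.0222), and were higher in both pairs. No member passed over all genes. A second probe of CD14 differed by 0.14 without and 0.65 with irradiation.

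No gene rose or fell with ORY1001 in limma over all genes (smallest adjusted p 0.853), and 670 had an unadjusted p under 0.05 where chance gives 742. The count was 2168 without the irradiated ORY1001 array, where the unirradiated one stands alone and is assumed to vary like the other groups. The pairs without and with irradiation correlated at -0.0948 across genes, with 929 and 69 genes at least 2-fold different. By the rule of size, FBN2, a fibrillin, was the 1 gene counted as higher in both (1.03 and 1.08, against untreated signals below detection) and FMO2 the 1 counted as lower in both. Independence gives 0.498 shared higher and 1.85 shared lower genes. In opposite directions went 6 genes, where it gives 1.97. Of the 195 2-fold genes with a second probe without irradiation, 124 (63.6%) had a second probe that differed in the same direction. Over all genes with a second probe the share was 56.6%.

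Genes named for ORY1001 were chosen for 1 direction in both pairs, and none passed over all genes. Among the higher genes, LAMA1, a laminin chain, was at 1.03 ± 0.23, the receptor ASGR1 at 0.95 ± 0.22, FCGBP at 0.80 ± 0.19 (its second probe at -0.06 without and 0.76 with irradiation) and TMEM79 at 0.75 ± 0.23. LOC100133076 was at 1.08 ± 0.23 and HSPC047 at 0.87 ± 0.19. The tight junction gene CLDN3 was at least 1.43-fold higher and, adjusted over the list alone, was the 1 of 16 epithelial genes that rose. FBN2 was at least 1.67-fold, PRPF39 at least 1.26-fold, LOC643274 at least 1.13-fold and LOC644144 at least 1.18-fold higher. Among the lower genes, FMO2, a monooxygenase, was at -1.18 ± 0.29, the cytokine IL16 at -0.84 ± 0.21, ZNF646 at -1.01 ± 0.36 and DNAJC2 at -0.85 ± 0.21. LOC391352 was at -1.27 ± 0.40, FLJ11783 at -0.96 ± 0.21 and BLID at -0.84 ± 0.24. FLJ35816 was not detected on either irradiated array, so no difference is given. LAMA1, LOC100133076, FMO2, LOC391352 and FLJ11783 were each not detected on 1 array of their lower side. LOC645626 was at least 1.63-fold, KIR3DL1 at least 1.60-fold, PBLD at least 1.49-fold and OR2AG2 at least 1.43-fold lower.

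Several lists differed without irradiation, on the array that stood apart from the others. There, immediate early genes had a median of 0.27 (percentile 99.6), with FOSB at 3.54, ATF3 at 2.33, ZFP36 at 2.22 and NR4A2 at 2.04. With irradiation the list had -0.02 (percentile 36.6). The second probe of NR4A2 was at 2.57 without irradiation and that of ATF3 at 0.54. Both genes had their lowest log2 signal on the unirradiated untreated array. NR4A2 was at 6.90 there, against 8.94 in unirradiated ORY1001 and 8.89 in unirradiated overexpressing cells. ATF3 was at 7.80 there and at 9.29 to 10.84 on the other arrays. A low untreated array may therefore add to these differences. In ORY1001 against untreated cells, TGF-beta and YAP targets had 0.37 without (99.8) and -0.14 with irradiation (1.26). Unfolded protein and amino acid stress genes had 0.28 (99.7) and 0.10 (99.4), and interferon-stimulated genes 0.23 (99.2) and 0.10 (99.8). In irradiated cells, ORY1001 had lower medians than untreated cells in G2/M and mitosis (-0.17, percentile 0), DNA double-strand break repair (-0.16, 0.30) and p53 targets (-0.16, 0.78). Hypoxia and glycolysis genes (0.17, percentile 100), luminal breast markers (0.30, 99.99) and epithelial genes (0.23, 99.9) had higher medians. Without irradiation none of these 6 lists stood apart. There, G2/M and mitosis was at 0.13 (87.3), DNA double-strand break repair at 0.10 (69.7) and p53 targets at -0.05 (17.2). Hypoxia and glycolysis was at 0.06 (67.3), luminal breast markers at 0.20 (86.7) and epithelial genes at -0.15 (9.96). G1/S and DNA replication genes also had a lower median with irradiation (-0.13, percentile 0.23) and did not stand apart without irradiation (0.10, 75.9). Blood markers, with CD14 among the 5 measured, had -0.18 (18.8) and 0.27 (97.2).

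Irradiation was compared with no irradiation to ask how the cells respond to 2 Gy of X-rays. Mitotic genes were lower as a list in all 3 LSD1 states, with medians of -0.15 in untreated, -0.26 in overexpressing and -0.44 in ORY1001 cells (average -0.25, all at percentile 0). Immediate early genes were higher in untreated (0.19, percentile 99.99) and overexpressing cells (0.26, 100), with 0.04 (77.2) in ORY1001 cells. The stress-induced transcription factor ATF3 rose by 1.54 ± 0.34 and JUNB by 0.90 ± 0.20, while the antiproliferative BTG2 fell at least 1.35-fold, to below detection, 3 of 31 members adjusted over the list alone (limma, adjusted p = 0.0497 each) and none over all genes. BTG2 is also a p53 target, and over that list its adjusted p was 0.125. ATF3 was at 2.49 in untreated, 1.56 in overexpressing and 0.56 in ORY1001 cells, and its second probe at 1.39, 1.12 and 1.44.

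No gene rose or fell with irradiation in limma over all genes (smallest adjusted p 0.356), and 1201 had an unadjusted p under 0.05 where chance gives 742. RNU4-1, a spliceosomal RNA, was the 1 gene that passed without either overexpression array (at least 4.43-fold higher, limma adjusted p = 0.00672), with no detected signal on the unirradiated untreated and ORY1001 arrays. The untreated and overexpressing pairs correlated at 0.351 across genes, with 18 shared genes at least 2-fold higher where independence gives 0.492. The ORY1001 pair, with 1046 genes at least 2-fold different against 132 and 136, correlated with them at 0.0466 and 0.0628. Of its 228 2-fold genes with a second probe, 149 (65.4%) had one that differed in the same direction, against 12 of 13 and 16 of 17. Over all genes with a second probe the shares were 54.7%, against 64.0% and 64.9%.

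Genes named for irradiation were chosen for 1 direction in all 3 pairs, and none passed over all genes. Among the higher genes, the spliceosomal RNAs RNU4-1, RNU2-1, RNU11 and RNU4ATAC were at 2.08 ± 0.20, 1.51 ± 0.22, 1.32 ± 0.21 and 1.05 ± 0.15. The small nucleolar RNAs SNORD3C, SNORD99 and SNORD14D were at 1.63 ± 0.34, 1.27 ± 0.17 and 1.08 ± 0.18. PPARGC1B, a coactivator of oxidative metabolism, was at 1.22 ± 0.18, HMOX2 at 1.03 ± 0.16, CNNM2 at 0.98 ± 0.16 and EYA3 at 0.92 ± 0.16. HDAC9 was at 1.15 ± 0.16, but its second probe differed by -0.61, -0.41 and -0.07 in the 3 pairs. Lower genes included PIF1, a DNA helicase, at -0.91 ± 0.15, the ubiquitin ligase G2E3 at -0.84 ± 0.15 and FLRT2 at -1.03 ± 0.17. MIR503HG was at -1.13 ± 0.19, C9orf152 at -1.12 ± 0.20, SLCO4A1-AS1 at -1.15 ± 0.20, TMEM187 at -0.98 ± 0.15 and TOGARAM2 at -0.98 ± 0.17. CMTM4 was at -0.94 ± 0.15, ELFN2 at -0.83 ± 0.15, CAVIN2 at -0.82 ± 0.15 and MAST2 at -0.80 ± 0.15. The second probe of CMTM4 was at -0.43, -0.24 and 0.08. On 1 or more arrays of their lower side, RNU4-1, RNU2-1, PPARGC1B, CNNM2, C9orf152 and TOGARAM2 were not detected.

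In untreated cells the highest genes were SNORD3A, SNORD3C and SNORD3D (2.63, 2.63 and 2.42), ATF3 and the orphan receptor NR4A2 (2.44). The lowest were APP (-1.70), SLCO4A1-AS1 (-1.63), and CYP4A11, HAAO and LOC728566, at least 2.08-fold, 1.93-fold and 1.61-fold lower. Each of the highest genes had its lowest log2 signal of all arrays on the unirradiated untreated array. SNORD3A was at 7.89 there and at 8.64 to 10.52 elsewhere, SNORD3C at 6.76 and at 7.51 to 9.39. SNORD3D was at 9.16 there and at 9.72 to 11.57 elsewhere. A low untreated array may therefore add to these differences. In overexpressing cells the highest were RNU4-1 (1.69), RRAD (1.66), CYP4B1 (1.60), ATF3 and FZD4 (1.55). The lowest there were GPC1-AS1, LINC02120, STC2, SHROOM2 and RTP2, at least 2.76-fold, 2.33-fold, 2.14-fold, 2.09-fold and 1.51-fold lower. In ORY1001 cells the highest were HMGA1P8 (4.13), NACC1 (3.53), POU2F2 (at least 6.83-fold), NHERF2 (3.14) and LOC642255 (3.07). The lowest were LOC100130332 (-2.98), LOC100130123 (-2.23), TOP3B (-2.16), ARHGAP33 (-2.11) and the mitotic activator CDC20 (-1.92). The second probes of NACC1 and LOC642255 were at 2.11 and 1.74. HMGA1P8 is a pseudogene of HMGA1, and its probe was not checked against the parent gene.

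Of 35 mitotic genes, 33 had a lower average after irradiation and 21 were lower in all 3 pairs, with none past the threshold adjusted over the list alone or over all genes. The kinase PLK1 had an average of -0.75 ± 0.33, with -0.20 in untreated, -0.23 in overexpressing and -1.82 in ORY1001 cells, whose unirradiated array stood apart. In the same order the kinesin KIF2C (-0.63 ± 0.21) was at -0.40, -0.32 and -1.18, and HMMR (-0.57 ± 0.22) at -0.13, -0.43 and -1.15. CDC20 (-0.61 ± 0.39) was at 0.06, 0.05 and -1.92. G1/S and DNA replication genes were higher in untreated (0.24, percentile 100) and overexpressing cells (0.13, 99.8), with -0.03 (58.5) in ORY1001 cells. Cyclin E2 (CCNE2) was at 0.74 ± 0.21, ORC1 at 0.66 ± 0.17 and RRM2 at 0.52 ± 0.15. The p53 targets had 0.10 (94.5), 0.06 (83.8) and -0.08 (47.3) and did not stand apart in any state, in a line that carries mutant p53. NF-kB and inflammatory cytokine genes had 0.19 (99.95), 0.26 (99.99) and -0.05 (53.9). CCL20, RELB and CCL2 rose by 1.03 ± 0.23, 0.87 ± 0.15 and 0.79 ± 0.18, 3 of 29 adjusted over the list alone and none over all genes. Interferon-stimulated genes had -0.08 (2.22), 0.09 (99.0) and -0.23 (1.42). Hypoxia and glycolysis genes had an average median of -0.12 (0.35), and ANGPTL4 fell by 0.96 ± 0.16, 1 of 32 adjusted over the list alone. Its second probe was at 0.11, -0.55 and -0.58 in the 3 states, against -0.98, -0.72 and -1.18 for the first. HES1 rose by 0.90 ± 0.18, 1 of 9 in its list, also adjusted over the list alone. No member of either list passed over all genes. Fibroblast markers, with 5 measured, had an average median of -0.40 (0.51), luminal breast markers of -0.02 (44.6) and blood markers of 0.15 (92.1), with none past the threshold. Luminal breast markers were at -0.22 (0.65) in untreated, where they stood apart, -0.09 (20.5) in overexpressing and 0.05 (71.1) in ORY1001 cells. DNA double-strand break repair genes had 0.15 (99.7), 0.00832 (61.1) and -0.16 (17.3).

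**Figure D3:**
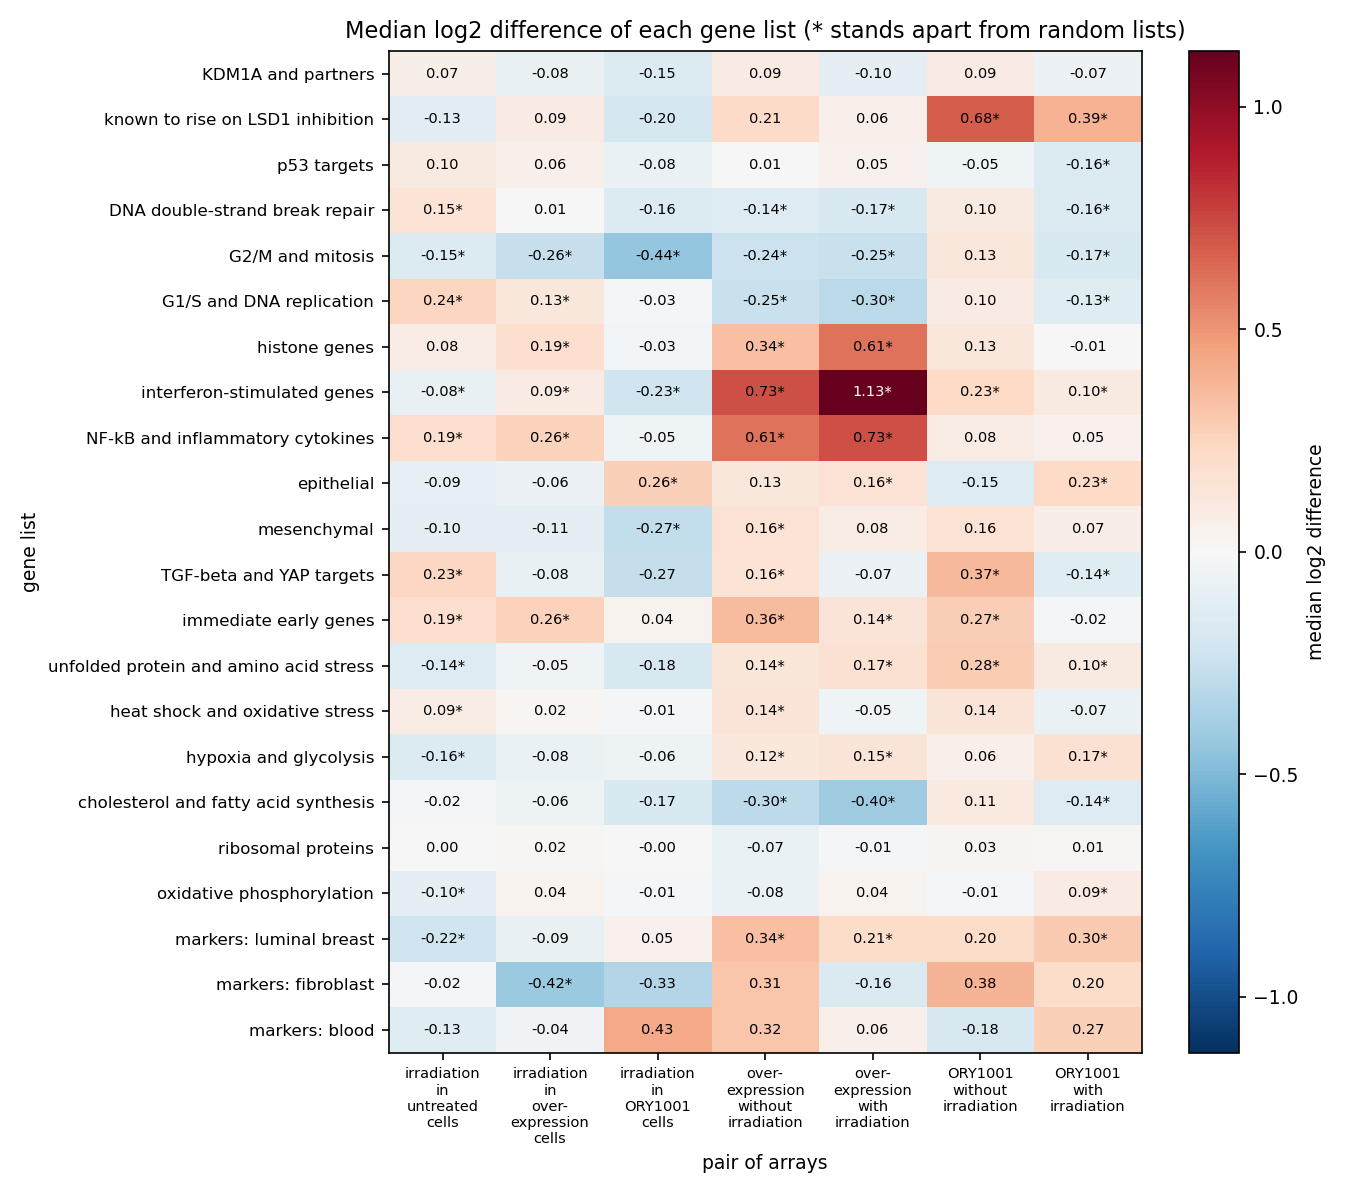
Median log2 difference of the measured members of each of the 22 gene lists (vertical axis) in each of the 7 pairs of arrays (horizontal axis), with color from lower (blue) to higher (red) and a star where the list stands apart from random lists. The interferon list is at 0.73 and 1.13 in the overexpression pairs.

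Overexpression and inhibition of LSD1 were set side by side to ask whether they move genes in opposite directions. Across genes, overexpression without irradiation and ORY1001 with irradiation, which share no array, correlated at 0.0902. Overexpression with irradiation and ORY1001 without correlated at 0.0421. Of the 227 and 369 genes at least 2-fold higher in these pairs, 14 were shared where independence gives 5.65, and of the 105 and 560 lower genes 7 were shared where it gives 3.96, while 9 went in opposite directions where it gives 11.2. In the first pair, 2 genes were shared as higher (0.223 by independence), 0 as lower (0.258) and 4 were opposite (0.650 by independence). Named after their values were seen, the shared ones were S100P and LOC100131831, and the opposite ones LILRB2, SNORD3A, SNORD3D and LOC441453. SNORD3A had a log2 signal of 9.30 in unirradiated overexpressing and 9.23 in irradiated ORY1001 cells, and SNORD3D of 10.3 and 10.4. The unirradiated and irradiated untreated arrays were at 7.89 and 10.52 for SNORD3A and at 9.16 and 11.57 for SNORD3D. The opposite signs of these genes therefore rest on the difference between the untreated arrays. HES1 was higher in both states, at 0.89 ± 0.22 with overexpression (limma, adjusted p = 0.0521 over the list alone) and 1.18 ± 0.22 with ORY1001. Both averages share the untreated arrays, and HES1 had its lowest log2 signal of the 6 arrays, 6.91, on the unirradiated untreated array, against 8.16 on the irradiated one and up to 9.01 elsewhere. Over the 22 lists, 7 pairs and 3 averaged effects, 93 of 220 medians stood apart, where lists of unrelated genes would give 11. Members of a list can vary together, and all comparisons use the same 6 arrays. The 11 is therefore not a chance level for these lists.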

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

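Among the tests below, those of an ORY1001 effect shared by both irradiation states, of low untreated arrays, of the vector, of a low unirradiated untreated array and of other splits were chosen only after the result was seen. Each group has 1 array, so the differences between groups given next were not tested. They stand out because the effects have opposite signs. The interferon list differed in irradiated minus unirradiated cells by -0.08 in untreated and 0.09 in overexpressing cells, a gap of -0.179. Between overexpressing and ORY1001 cells (-0.23) the gap was 0.322. For ORY1001 against untreated cells, the TGF-beta and YAP list was at 0.37 without and -0.14 with irradiation, a gap of 0.502. In that comparison ARHGAP33 had a gap of 2.27 (1.23 against -1.04) and HMGA1P8 of -4.89 (-3.63 against 1.26). The gap of LINC02120 between the overexpression pairs was 2.36 (1.17 against -1.19). LOC100130332 differed after irradiation by 1.08 in overexpressing and -2.98 in ORY1001 cells, a gap of 4.06. LINC02120 was not detected on the irradiated and LOC100130332 not on the unirradiated overexpression array, so both gaps include a signal not above background and their sizes are not exact.

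The unirradiated ORY1001 array stood apart from the other arrays. Probe GC content as the whole trend is argued against, since 93.6% of the 2-fold genes stayed 2-fold different after correction, and dim probes too, since 34.9% lay in the lowest tercile of signal. An ORY1001 effect shared by both irradiation states, as the whole trend, is argued against by a correlation of -0.095 between the pairs. That correlation cannot exclude a smaller shared effect, since the pairs held 929 2-fold genes without and 69 with irradiation. A fault of single probes stays open, since 63.6% of second probes differed in the same direction, against 56.6% over all genes with a second probe. The 63.6% lay between bounds of 60% and 80% set before this share was seen, although both probes of NACC1 had been seen. An ORY1001 effect that is gone after irradiation cannot be told apart from a fault in the RNA or the array by 1 array per group, and the list of genes known to rise on LSD1 inhibition decides little, since it stood at percentile 99.9 without and still at 99.96 with irradiation.

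Interferon and cytokine genes were higher in both overexpression arrays. Low untreated arrays are argued against, since irradiated overexpressing cells also exceeded irradiated ORY1001 cells, with a median of 0.824 for the interferon list. Cells of the luminal breast type stay open as a hypothesis, with TFF1 and AGR2 higher. The keratins KRT8, KRT18 and KRT19 had a median difference of 0.086, under the bound of 0.2 set beforehand, but that bound was wrong because untreated cells already had them at 10.49, 8.82 and 12.09 against 7.79 for the median gene, so a small share of luminal cells would be hidden. The vector DNA and LSD1 itself cannot be told apart, because no array had an empty vector and the KDM1A probe differed by -0.079.

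Immediate early genes were higher after irradiation in untreated cells. The list was also higher against the same unirradiated untreated array in unirradiated overexpressing cells, with a median of 0.359, and in unirradiated ORY1001 cells (0.27). After irradiation it stood apart in overexpressing cells (0.26), which do not use that array, and not in ORY1001 cells (0.04). A low unirradiated untreated array may therefore add to the difference, and it cannot be told apart from a response to irradiation, which stays open too.

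For irradiation, 0 genes passed over all genes, and the highest count among the other splits of the 6 arrays into 3 and 3 was 388. With 0 in the real grouping, all 10 of the 10 splits necessarily had as many, and 10 splits are too few for a share under 0.05. The splits with the highest count put both untreated arrays together with 1 ORY1001 array, against both overexpression arrays and the other. The model kept LSD1 state, so that count rests on the difference between the ORY1001 arrays alone. Of these, the unirradiated one stood apart from the other arrays.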

How the results depend on the processing

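Of the 21 settings, the probe GC correction was chosen after seeing the data. No gene or list median past its threshold reversed, but in 1 pair the balance of higher and lower genes turned, as given last. Among list medians, 57 values under alternatives had another sign than the main one, all of medians that did not stand apart, and so had 5 values of KDM1A, all of differences near 0. Of the counts and correlations, 152 values under alternatives stayed close and 59 moved. Of the list medians 2075 stayed within their spread and 115 moved, and of the named genes 866 and 214. The 93 list medians that stood apart kept their sign in all 928 alternatives. The cause of the moves was not tested unless stated. Signals near background limit the folds of dim genes, which a higher offset shrinks by construction. No scaling moved the median of all genes by more than 0.0903.

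The 3 genes called for overexpression became 35 with an offset of 50, 35 without background correction, 14 with median scaling, 43 with detection at 0.05 on 1 array, 41 with trend and robust moderation and 8 without irradiation in the model. They became 0 with the deposited signals, without a detection filter and with the mean of a gene's probes. Leaving out each array in turn gave 0 to 481 genes for overexpression, 0 to 2168 for ORY1001 and 0 to 1 for irradiation. A lone array was then assumed to vary like the other groups.

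Genes at least 2-fold different are given in the order irradiation in untreated, overexpressing and ORY1001 cells, overexpression without and with irradiation, and ORY1001 without and with irradiation. With an offset of 50 they numbered 26, 28, 531, 109, 160, 468 and 8. Without background correction they numbered 27, 29, 533, 105, 161, 473 and 10. With the deposited signals they numbered 407, 451, 1690, 622, 676, 1562 and 295. A 1.5-fold rule gave 1037, 1072, 3888, 1431, 1624, 3623 and 773, and a 3-fold rule 12, 5, 181, 37, 70, 126 and 4, by construction. Detection on all 6 arrays left fewer genes, with 62 and 68 for irradiation in untreated and overexpressing cells, 156 for overexpression without irradiation and 24 for ORY1001 with irradiation.

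The percent of these genes that were higher moved too. For irradiation in untreated cells 76.9%, 77.8% and 71.0% were higher with the offset of 50, without background correction and with detection on all arrays, and 53.1% with the deposited signals, against 62.1% in the main setting. For irradiation in overexpressing cells these were 85.7%, 82.8% and 75.0%, but 44.3% with median scaling and 35.0% with the deposited signals, where lower genes were more. For overexpression without irradiation they were 86.2% and 86.7% with the first pair of settings and 78.1% with median scaling, and with irradiation 82.5% and 82.0%, but 58.7% with the deposited signals. The deposited signals gave 46.4% for ORY1001 with irradiation. Without a detection filter the correlation of the overexpression pairs was 0.399 and that of irradiation in untreated and overexpressing cells 0.243.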

Other observations

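The tests of hypotheses stand with the results above, and the values here were chosen after they were seen. APP, the amyloid precursor, was lower after irradiation in untreated cells by both of its probes, at -1.70 and -1.57, in overexpressing cells at -0.46 and -0.38, and in ORY1001 cells at -0.68 and -1.16. It was also lower than on the unirradiated untreated array without irradiation, at -0.96 and -0.78 in overexpressing and -0.95 and -0.42 in ORY1001 cells. The brighter probe had a log2 signal of 9.78 on that array and of 8.08 to 8.83 on the other 5. In unirradiated ORY1001 cells the invariant chain CD74 was lower than in untreated cells by both probes, at -1.06 and -1.20, and so was the collagen COL6A2, at -1.05 and -1.76. VEGFA, a target of hypoxia signalling, was higher there by both probes, at 1.89 and 1.61, and so was PTGS2, at 1.34 and 1.19. Probes of UHRF1 went apart in the same pair, at 0.41 and -1.41. These pairs have no test.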
